A study of Arabidopsis thaliana with 20 samples.

How the data were processed

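Root tips of Arabidopsis thaliana seedlings were profiled on Affymetrix ATH1-type arrays with 22810 probe sets. Per the labels, seedlings carried a FLAG-tagged ribosomal protein L18 under 1 of 4 promoters, and messenger RNA bound to tagged ribosomes was immunopurified from the tips, so that each line samples the polysomal RNA of the cells in which its promoter is active. The labels place the activity of pSCR in the endodermis and of pSHR and pWOL in the vascular tissue, and p35S is the broadly active promoter. Total RNA came from the lysates that also gave the p35S polysomes. Seedlings 7 days old were held for 2 h in argon (hypoxia) or in air (control), and the terminal 1 cm of the root was taken. Amplification started from 400 pg of RNA and used 2 rounds, per the labels' protocols. Strong amplification of small inputs can lower or raise transcripts unevenly, and shortens products towards the 3 prime end.

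The deposited values are log2 expression per probe set. Per the submitters' processing notes the authors used RMA and the Bioconductor package affy; versions and the chip definition are not given in the sources used here. The values ran from 3.35 to 14.88, and the array medians from 6.41 to 6.55, so no further scaling was applied in the main analysis. RMA compresses small values towards a floor, so folds of weakly expressed transcripts are understated. The number of arrays limits the precision: 20 arrays formed 10 groups of 2 (5 RNA populations in 2 treatments). The labels call the arrays of a group replicates without saying that they came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. Replicates correlated at r = 0.965 to 0.984 across probe sets, and no array was a duplicate of another.

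The 64 control probe sets were left out, and 22746 were tested. Genes were named only through the supplied annotation table of the platform: 13513 tested probe sets had 1 gene, 503 had several and 8730 had none listed. Of the single-gene probe sets, 13436 matched the TAIR10.1 gene table by gene ID; the others kept the symbol of the annotation. The table names few genes that carry a symbol (15.5% of those in the gene table, against 68.2% of those known by locus code alone), so probe sets of ADH1, SCR, SHR, WOL and RPL18 were not analysed here by name. No genome build is named for the values, so no coordinates are given.

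Differences were tested with limma (version 3.58.1 in R 4.3.3) on the log2 values. A model of 10 group means was fitted to all 20 arrays, leaving 10 residual degrees of freedom, with empirical Bayes moderation (prior degrees of freedom 3.30) and Benjamini-Hochberg adjustment within each of 18 comparisons; a probe set was called at an adjusted p below 0.05. The comparisons were hypoxia against control in each of the 5 populations, the mean of the 4 polysomal hypoxia differences, the difference of each other line's hypoxia difference from that of p35S, a joint F test of these on 3 degrees of freedom, p35S polysomal against total RNA in each treatment and the difference between treatments, and the lines against each other in air. Errors beside log2 differences are standard errors of the model.

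Gene lists were fixed before the data were examined (302 entries, of which 49 had a named probe set). The low-oxygen response list was named in literature that partly used these very samples, so its direction is not independent evidence. Lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with the probe set of highest mean per gene, and 7 lists in 17 comparisons gave a family of 119 tests adjusted together. Of 33 list calls, 11 held with an estimated correlation. Fry was run as an alternative. The whole class III peroxidase family and the plastid-encoded genes were added as lists after the data were seen. The genes named in the text follow a rule fixed beforehand: among single-gene probe sets with adjusted p below 0.05 and no overlap between the arrays of the groups, which chance gives in 33.3% of splits of 2 against 2 (for tests of differences between differences, the adjusted p alone), the 12 largest log2 differences in each direction for the mean polysomal hypoxia comparison, the lines against p35S and p35S polysomal against total RNA in air, 5 per direction elsewhere, the 10 smallest p of the F test, and every measured member of a list. BPC1's neighbour ATMAP65-6 and the added lists' genes were chosen after their values were seen.

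The calling was tested on simulated log2 values with the means and spreads of all 22746 probe sets. For p35S hypoxia, 96 of 100 planted changes of 2 and 39 of 100 of 1 log2 unit were recovered; for the mean over the 4 lines, 100 of 100 and 95 of 100; for the pWOL against p35S difference, 74 of 100 and 9 of 100. Alternatives were a replicate block, a block of the shared lysate, the arrays of the compared groups alone, leaving out the dimmest 25% of probe sets, quantile normalization, median centring, a trended robust moderation, single-gene probe sets only, and leaving out each array. Replicate numbers are shared between groups in the labels but were not taken as pairs; the check is given with the alternatives. Crossed lysate pairs and leaving out both pSHR arrays of a number were added after the data were seen.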

Results

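The data are 20 arrays of RNA from Arabidopsis root tips, 2 in each of 10 groups. Total RNA and ribosome-bound (polysomal) RNA of 4 promoter lines (p35S, pSCR, pSHR, pWOL) were each sampled in air and after 2 h of argon hypoxia. The labels assign pSCR to the endodermis and pSHR and pWOL to the vascular tissue, and p35S is broadly active. Endodermal and vascular follow these labels. The array medians lay between 6.41 and 6.55 log2 units. As a sign of RNA quality, the 3 prime minus 5 prime difference of the GAPDH control probe sets was 3.68 ± 0.40 (SD, n = 4) log2 units in p35S arrays. It was 4.55 ± 0.29 in total RNA, 4.37 ± 0.51 in pSCR, 4.54 ± 0.15 in pSHR and 4.58 ± 0.33 in pWOL (SD, n = 4 each). The 25S ribosomal RNA control read 10.18 in pSCR hypoxia replicate 2 and between 12.69 and 14.34 in all other arrays.

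What oxygen shortage does to the translated transcripts of the root tip was addressed with the mean hypoxia difference over the 4 polysomal lines (8 against 8 arrays). All 13 measured members of the low-oxygen response list rose, over all probe sets and adjusted over the list alone, with a median log2 difference of 4.88. AT5G10040 rose by 7.07 ± 0.21 log2 units, AT4G24110 by 6.77 ± 0.21 and AT4G10270 by 6.61 ± 0.15. AT3G10040 (HRA1, a trihelix transcription factor) rose by 6.37 ± 0.16, which is 82.8-fold. CML38, a calmodulin-like calcium sensor, rose by 4.54 ± 0.25 and AT1G33055 by 5.05 ± 0.15. The camera adjusted p of the list was 3.45e-35, and the adjusted p was 0.00123 with an estimated correlation. The list comes from literature that partly used these very samples, so its rises are not independent evidence of direction. Further large rises were those of AT3G27220 (5.18 ± 0.16), AT4G33560 (4.88 ± 0.24), AT3G23170 (4.78 ± 0.23) and AT1G19530 (4.63 ± 0.17). AT5G26200 rose by 4.61 ± 0.10 and WRKY22, a WRKY transcription factor, by 4.54 ± 0.16.

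**Figure D1:**
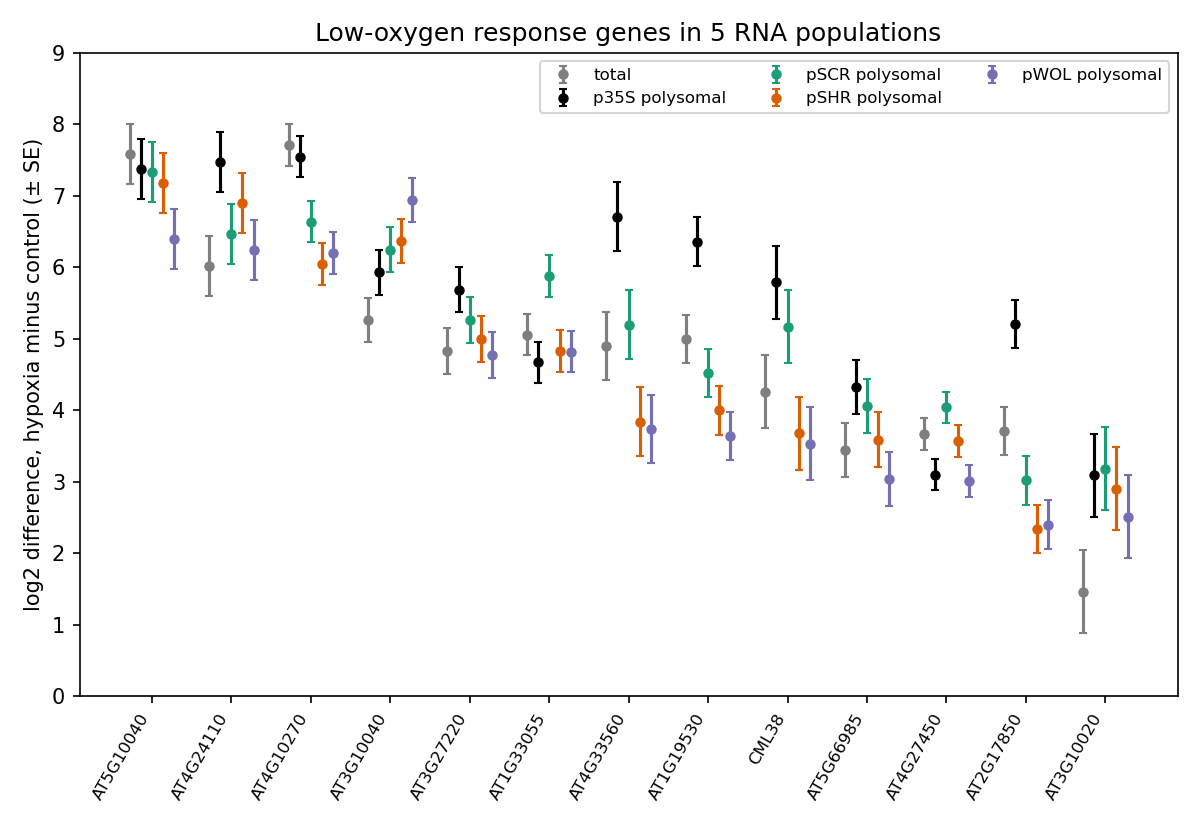
Log2 difference in expression, hypoxia minus control (vertical axis), for the 13 measured low-oxygen response genes (horizontal axis) in total RNA and in the polysomal RNA of the 4 lines; points are differences of 2 against 2 arrays and bars are standard errors of the model. The points lie above 0, from 1.46 for AT3G10020 in total RNA to 7.71 for AT4G10270 in total RNA.

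Of the fermentation and sugar breakdown list, 2 of 4 measured genes rose in the same comparison, and 2 adjusted over the list alone. PDC2, a pyruvate decarboxylase, rose by 3.67 ± 0.15 log2 units and AT4G17260, lactate dehydrogenase, by 2.28 ± 0.11. PPDK (0.51) and GAPC2 (0.10) did not pass. The list's adjusted p was 2.07e-04, and the adjusted p was 0.0475 with an estimated correlation. All 4 heat shock genes rose, over all probe sets and adjusted over the list alone. AT5G48570 rose by 1.98, AT5G37670 by 1.94, AT1G53540 by 1.87 and ATHSP22.0 by 0.59. The list's adjusted p was 5.10e-05, and adjusted p = 0.0992 with an estimated correlation. Of 5 reactive oxygen and mitochondrial stress genes 2 rose, and 4 adjusted over the list alone. STZ, a zinc finger repressor, rose by 1.90 and WRKY53 by 0.69. The adjusted p of this list was 0.00497, and adjusted p = 0.0602 with an estimated correlation. The cytosolic ribosomal proteins (0 of 4 genes called), the cell cycle genes (1 of 3) and the cell wall genes (1 of 4) passed no list test, with adjusted p of 0.353, 0.282 and 0.265. AUR2, an Aurora kinase, differed by -0.95 and EXPA4, an expansin, by -1.60, and both were called.

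Of the 12 single-gene probe sets with the strongest falls and no overlap between the arrays, 4 belong to the class III peroxidase family. Its enzymes act in the cell wall. AT1G34510 fell by 3.1 ± 0.29 log2 units, and AT3G49960 (-2.78 ± 0.30), AT1G30870 (-2.69 ± 0.28) and AT2G35380 (-2.41 ± 0.24) fell as well. Another member, AT2G39040 (-2.79 ± 0.36), was called but its arrays overlapped. The others of the 12 were AT3G50300 (-3.08 ± 0.13), AT3G45700 (-2.78 ± 0.25), AT4G18630 (-2.26 ± 0.19) and AT5G01210 (-2.2 ± 0.17). They also include AT1G72140 (-2.06 ± 0.18), AT3G62590 (-2.05 ± 0.20), AT2G17590 (-1.99 ± 0.14) and AT3G50400 (-1.97 ± 0.14). Among markers of cell types, the root hair expansins EXPA7 (-2.23) and EXPA18 (-1.74), JKD (-0.75), PHV (-0.52) and the cortex marker AT1G09750 (-0.57) fell. GSO1 (-0.32), LHW (0.08), OPS (-0.15), AT1G62500 (0.10) and RCA (-0.11) did not pass. RTE1, an ethylene signalling gene, differed by -0.97 and was called, and AKINBETA1 (0.35) was not. In all, 4669 probe sets were called, 2203 higher and 2466 lower, with 637 and 434 of them by at least 1 log2 unit. Over the 13513 single-gene probe sets alone the count was 2328.

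**Figure D2:**
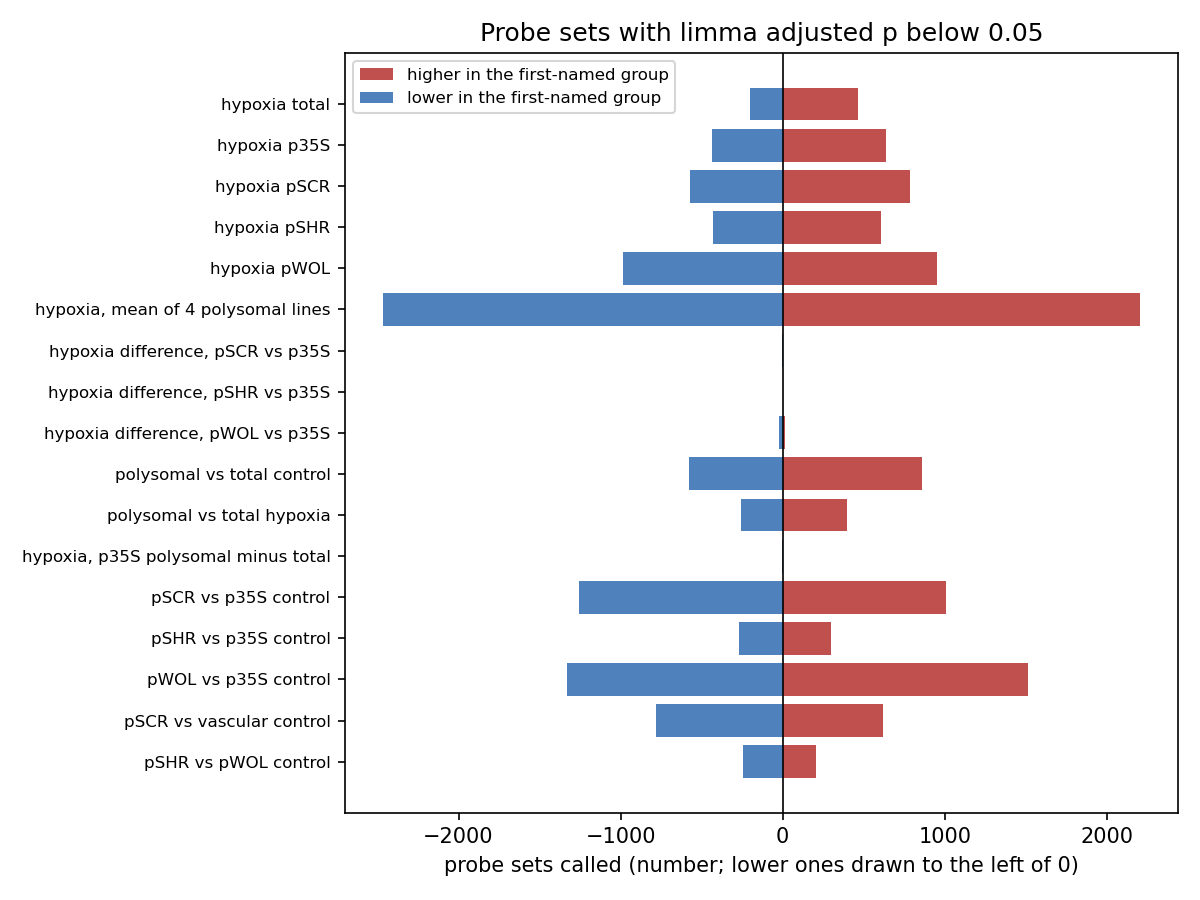
Probe sets with a limma adjusted p below 0.05 in each comparison (horizontal axis: number of probe sets, with lower ones drawn to the left of 0), higher in the first-named group or in hypoxia in red and lower in blue. The mean hypoxia difference over the 4 polysomal lines has 4669 calls, while the differences of pSCR, pSHR and pWOL from p35S in their response to hypoxia have 6, 0 and 36.

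Each population's response was also tested alone, with 2 against 2 arrays. In total RNA AT4G10270 rose by 7.71 ± 0.29 log2 units, AT5G10040 by 7.58 ± 0.42 and AT4G24110 by 6.02 ± 0.42. AT3G10040 (5.26 ± 0.31) and AT1G33055 (5.06 ± 0.29) followed. AT3G07070 (-3.23 ± 0.40), AT3G50300 (-3.06 ± 0.26), AT1G34510 (-2.96 ± 0.58), AT4G25250 (-2.82 ± 0.47) and AT3G01730 (-2.53 ± 0.18) fell. Of the low-oxygen list 12 of 13 members rose (13 adjusted over the list alone), with a median of 4.90. Of the fermentation list 2 of 4 genes rose (3 adjusted over the list alone; list adjusted p = 4.16e-07), with PDC2 up by 3.46. Of the heat shock list 1 of 4 rose (2 adjusted over the list alone), with a list adjusted p of 7.23e-04, and adjusted p = 0.161 with an estimated correlation. The oxidative stress list was called with adjusted p of 0.00178, and 0.0475 with an estimated correlation. In total RNA 464 probe sets rose and 201 fell, 665 together. The count was 443 and 334 without control replicates 1 and 2, and 367 and 309 without hypoxia replicates 1 and 2.

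In p35S polysomes AT4G10270 rose by 7.55 ± 0.29, AT4G24110 by 7.48 ± 0.42 and AT5G10040 by 7.38 ± 0.42. AT4G33560 (6.71 ± 0.48) and AT1G19530 (6.36 ± 0.34) followed. AT4G18630 (-3.23 ± 0.38), AT3G01260 (-2.65 ± 0.50), AT5G51470 (-2.59 ± 0.33), AT1G08280 (-2.56 ± 0.33) and AT1G23160 (-2.55 ± 0.36) fell. All 13 low-oxygen genes rose, PDC2 rose by 3.59, and AT1G53540, a small heat shock protein, by 2.58. The fermentation list was called with adjusted p of 1.12e-04, and 0.0466 with an estimated correlation. The heat shock list had 0.00161, and adjusted p = 0.183 with an estimated correlation. The oxidative stress list had 0.00547, and adjusted p = 0.0602 with an estimated correlation. The fit called 638 higher and 436 lower, 1074 together. This became 520 and 578 without control replicates 1 and 2, 514 without hypoxia replicate 2, and 342 from the 4 compared arrays alone.

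In pSCR (endodermis) AT5G10040 rose by 7.34 ± 0.42, AT4G10270 by 6.64 ± 0.29 and AT4G24110 by 6.47 ± 0.42. AT3G10040 (6.25 ± 0.31) and AT1G33055 (5.88 ± 0.29) followed. AT3G45700 (-3.70 ± 0.50), AT1G34510 (-3.18 ± 0.58), AT2G39040 (-2.93 ± 0.73), AT3G62590 (-2.81 ± 0.39) and AT3G50300 (-2.71 ± 0.26) fell. GSO1, a receptor kinase of the endodermal barrier, differed by -1.37 and AUR2 by -1.59, and both were called. All 13 low-oxygen genes rose and PDC2 rose by 3.56. The fermentation list was called with adjusted p of 8.50e-04, and adjusted p = 0.0602 with an estimated correlation. The heat shock list had 0.00610, and adjusted p = 0.212 with an estimated correlation. The oxidative stress list did not pass (adjusted p = 0.470). The fit called 784 higher and 572 lower, 1356 together. Higher calls were 57.8%, and 48.8% with arrays centred on their medians. Hypoxia replicate 2 is the array with the low 25S reading, and without it the count was 475. It was 521 without control replicate 1 and 228 from the 4 compared arrays alone.

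In pSHR (vascular) AT5G10040 rose by 7.18 ± 0.42, AT4G24110 by 6.90 ± 0.42 and AT3G10040 by 6.37 ± 0.31. AT4G10270 (6.05 ± 0.29) and AT3G27220 (5.00 ± 0.32) followed. The peroxidases AT1G34510 (-4.07 ± 0.58), AT3G49960 (-3.91 ± 0.60), AT1G30870 (-3.82 ± 0.57) and AT2G39040 (-3.06 ± 0.73) fell, and so did AT3G50300 (-3.83 ± 0.26). All 13 low-oxygen genes rose. Of 4 heat shock genes 3 rose (4 adjusted over the list alone), with AT5G37670 at 3.35. The list's adjusted p was 2.97e-06, and adjusted p = 0.0602 with an estimated correlation. The fermentation list was called with 0.00484, and adjusted p = 0.105 with an estimated correlation. The oxidative stress list had 0.00523, and adjusted p = 0.0602 with an estimated correlation. Without hypoxia replicate 1 these 2 lists were not called (0.0927 and 0.101). The fit called 609 higher and 428 lower, 1037 together. The count was 514 without control replicate 2, 382 without hypoxia replicate 2, 244 without both arrays numbered 2 (added after the arrays were seen to stand apart) and 20 from the 4 compared arrays alone.

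In pWOL (vascular) AT3G10040 rose by 6.94 ± 0.31, AT5G10040 by 6.4 ± 0.42 and AT4G24110 by 6.24 ± 0.42. AT4G10270 (6.20 ± 0.29) and AT1G33055 (4.82 ± 0.29) followed. SETH6 (-3.52 ± 0.46), AT3G50300 (-3.45 ± 0.26), AT3G45700 (-3.36 ± 0.50), AT1G80320 (-3.35 ± 0.36) and AT2G17590 (-3.26 ± 0.28) fell. All 13 low-oxygen genes rose and PDC2 rose by 4.07. The fermentation list was called with adjusted p of 1.21e-05, and 0.0255 with an estimated correlation. The heat shock list had 0.00523, and adjusted p = 0.212 with an estimated correlation. The oxidative stress list had 0.0272, and adjusted p = 0.114 with an estimated correlation. Without control replicate 2 these 2 lists were not called (0.0548 and 0.0860). The fit called 950 higher and 987 lower, 1937 together. Higher calls were 49%, and 56.9% with arrays centred on their medians. The count was 871 and 841 without control replicates 1 and 2, and 812 and 788 without hypoxia replicates 1 and 2.

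Of 1698 probe sets that rose in any of the 5 populations, 212 rose in all 5 and 958 in 1 alone. Of 1745 that fell, 37 fell in all 5. Independent lists would share 5.02e-04 and 7.91e-05 probe sets, and each population has its own control arrays. The lists are not independent, since the fit shares the spread of each probe set, and total and p35S RNA share lysates. These values are therefore not a fair expectation. The log2 changes of the populations correlated across probe sets at 0.50 (p35S and pWOL) to 0.71 (total and pSHR), and genes are not independent replicates. Probe sets that rose in 1 population and fell in another numbered 15. A call in 1 population alone does not show that the others differ. With 2 against 2 arrays, 39 of 100 planted changes of 1 log2 unit were recovered for p35S hypoxia.

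Whether the lines differ in their response was tested as the difference of their hypoxia differences from that of p35S. In pWOL, AT2G32190 differed by -3.84 ± 0.51, its hypoxia difference being 3.47 in p35S and -0.37 in pWOL. In total RNA, pSCR and pSHR it was 0.55, 0.71 and 0.08, so p35S rather than pWOL stood apart for this gene. SETH6 (-4.16 ± 0.65), AT3G07230 (-2.82 ± 0.44), AT2G17850 (-2.81 ± 0.48) and AT3G03150 (-2.76 ± 0.49) were also more negative in pWOL than in p35S. AT3G18190, a chaperonin subunit, differed by 2.37 ± 0.40, AT1G50920 by 2.11 ± 0.32 and AT1G15480 by 1.93 ± 0.29. ATERDJ3B, a co-chaperone of the endoplasmic reticulum, differed by 1.85 ± 0.33 and SLOMO by 1.67 ± 0.26. For AT3G18190 the pWOL mean was 8.81 in air and 10.74 in hypoxia, against 10.84 and 10.40 in p35S. For AT1G15480 it was 5.63 and 6.83, against 7.12 and 6.4. In pSCR, AT5G23340 differed by 2.04 ± 0.28, AT3G54080 by 1.74 ± 0.23, AT1G36070 by -1.83 ± 0.27 and AT4G26460 by -1.41 ± 0.19. The limma counts were 36 probe sets in pWOL (15 more positive, 21 more negative), 6 in pSCR (3 and 3) and 0 in pSHR, where 2291 had an unadjusted p below 0.05. The share of more positive calls in pWOL was 41.7%, and 52.9% with arrays centred on their medians. The pSCR count was 0 without p35S control replicate 1 or 2, p35S hypoxia replicate 2 or pSCR hypoxia replicate 2. It was 2 without pSCR control replicate 1, 16 without p35S hypoxia replicate 1, 33 without pSCR hypoxia replicate 1, and 0 without the dimmest 25% of probe sets or from the compared arrays alone. The pWOL count was 0 without p35S control replicate 1 or 2 or p35S hypoxia replicate 2, 156 without p35S hypoxia replicate 1, and 0 from the compared arrays alone. It was 2 and 7 without pWOL control replicates 1 and 2, and 1 and 2 without pWOL hypoxia replicates 1 and 2. The pSHR count was 11 without p35S hypoxia replicate 1, 6 without pSHR control replicate 1, 55 without pSHR hypoxia replicate 1, 7 with trended robust moderation and 2 without both pSHR arrays numbered 1.

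The low-oxygen list was called as different from p35S in both vascular lines and not in pSCR. It was named in literature that partly used these very samples, so its differences between lines are not independent evidence either. In pWOL its 13 genes had a median difference of -1.24 from p35S, with 2 called (AT1G19530 at -2.72 and AT2G17850 at -2.81) and 5 adjusted over the list alone. The camera adjusted p was 5.10e-05, and adjusted p = 0.175 with an estimated correlation. In pSHR the median was -0.69, with 0 called over all probe sets by limma and 5 adjusted over the list alone. The adjusted p was 8.50e-04, and adjusted p = 0.212 with an estimated correlation. Fry gave 0.0674, and without pSHR hypoxia replicate 1 the median was -0.19 with an adjusted p of 0.0792. CML38 had 5.79 in p35S against 3.68 in pSHR and 3.53 in pWOL, and AT4G33560 had 6.71 against 3.84 and 3.74, differences that did not pass over all probe sets. Members went both ways: AT3G10040 differed by 1.02 in pWOL and 0.44 in pSHR, AT1G33055 by 0.15 and 0.16, and AT4G27450 by -0.10 and 0.47, none of which passed. In total RNA CML38 had 4.26 and AT4G33560 had 4.90. In pSCR the low-oxygen list had a median difference of -0.44 from p35S. Adjusted over the list alone, 2 genes were more positive and 2 more negative there. AT2G17850 (-2.19), AT1G19530 (-1.84) and AT4G33560 (-1.51) were below p35S, and AT1G33055 (1.22) and AT4G27450 (0.94) above. None of these passed over all probe sets. Whether pSCR and the vascular lines differ in this list's response was not tested. In pSCR the oxidative stress list had a median difference of -0.86 (0 of 5 called, 1 adjusted over the list alone), with STZ at 3.26 in p35S and 0.62 in pSCR. Its adjusted p was 0.0337, and adjusted p = 0.129 with an estimated correlation. This call was lost without p35S control replicate 2 (0.0744), p35S hypoxia replicate 2 (0.209), pSCR control replicate 2 (0.0869) or pSCR hypoxia replicate 2 (0.0652).

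The joint F test of the 3 differences called 0 probe sets by limma, where 2902 had an unadjusted p below 0.05. The smallest adjusted p was 0.0830, that of AT2G32190, AT1G36070 and AT4G26460. AT3G54080 and AT1G15480 (0.105), AT2G16710 (0.112), AT5G23340, the peroxidase AT4G08780, AT1G72940 and SLOMO (0.122) followed. The count was 4 without p35S hypoxia replicate 1, 1 and 7 without pSCR control replicates 1 and 2, 4 without pSCR hypoxia replicate 1 and 1 without pWOL hypoxia replicate 1. It was 14 with trended robust moderation, 1 from the compared arrays alone and 4 without both pSHR arrays numbered 1.

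To ask which transcripts were bound to ribosomes out of proportion to their total level, p35S polysomal RNA was set against total RNA. Total RNA comes from all cells of the tip, and p35S polysomes come from the cells in which p35S is active. Ribosome binding and the cells sampled therefore cannot be told apart here, in either treatment. The 3 prime bias of the arrays, given below, differed as well. In air, AT3G19430 (2.95 ± 0.59 log2 units), AT2G43800 (2.74 ± 0.36), AT1G52050 (2.69 ± 0.56), AT3G51720 (2.65 ± 0.44), AT2G40480 (2.60 ± 0.30) and AT4G18630 (2.56 ± 0.38) were higher in polysomes. So were AT5G35200 (2.53 ± 0.42), AT5G07030 (2.52 ± 0.39), AT1G23160 (2.50 ± 0.36), AT5G54370 (2.48 ± 0.60), AT3G49190 (2.42 ± 0.37) and AT5G62550 (2.38 ± 0.22). PDF2.5, a plant defensin (-4.10 ± 0.47), AT1G05575 (-3.27 ± 0.51), AT1G73620 (-3.21 ± 0.55), AT2G14900 (-3.12 ± 0.36), AT4G33730 (-2.93 ± 0.40) and DI21 (-2.92 ± 0.41) were lower. So were XTH21, a xyloglucan-modifying enzyme (-2.90 ± 0.34), the plastid gene psbJ (-2.89 ± 0.69), AT5G57785 (-2.77 ± 0.39), AT2G47540 (-2.76 ± 0.28), AT4G30320 (-2.74 ± 0.31) and AT3G22540 (-2.72 ± 0.44). Of cell type markers, EXPA7 (-2.47) and EXPA18 (-2.42) of root hairs and the cortex marker AT1G09750 (-2.38) were lower, and the stele genes PHV (2.22) and LHW (1.53) higher. In these air arrays the 3 prime minus 5 prime difference was 3.87 and 3.16 in p35S and 4.72 and 4.55 in total RNA.

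The fermentation list was higher in polysomes in air, with a median of 0.84, GAPC2 called (0.95) and 2 genes adjusted over the list alone. Its adjusted p was 0.00534, and adjusted p = 0.111 with an estimated correlation. The cytosolic ribosomal proteins did not pass (adjusted p = 0.247), with AT3G53890 at -1.53 and AT2G19730 at -1.25. Both RNAs came from the same lysates, and since the labels do not tie arrays to lysates they were tested as independent, here and in the hypoxia and difference tests. In air 859 probe sets were higher and 579 lower, 1438 together. The count was 660 and 429 without total replicates 1 and 2, and 570 and 464 without p35S replicates 1 and 2.

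Under hypoxia AT3G19430 (2.85 ± 0.59), AT5G60530 (2.75 ± 0.52), AT1G50060 (2.74 ± 0.61), AT4G32860 (2.67 ± 0.57) and AT1G67870 (2.58 ± 0.58) were higher in p35S polysomes than in total RNA. XTH21 (-2.62 ± 0.34), AT3G22540 (-2.53 ± 0.44), DI21 (-2.44 ± 0.41), PDF2.5 (-2.39 ± 0.47) and AT2G14900 (-2.09 ± 0.36) were lower. The cortex marker AT1G09750 (-1.85) and the root hair gene EXPA18 (-1.74) were lower and the stele gene PHV (0.98) higher. In these hypoxia arrays the 3 prime minus 5 prime difference was 4.08 and 3.62 in p35S and 4.79 and 4.14 in total RNA. The low-oxygen list was higher in polysomes, with a median of 0.90, 2 of 13 called (AT4G33560 at 1.92 and AT1G19530 at 1.73) and 4 adjusted over the list alone. Its adjusted p was 0.00140, and adjusted p = 0.230 with an estimated correlation. Fry gave 0.0535. The literature that named this list partly used these samples, so its shift here is not independent evidence. The fermentation list had a median of 0.60 (0 of 4 called, 2 adjusted over the list alone) and adjusted p of 0.0272, and adjusted p = 0.183 with an estimated correlation. It was not called without total hypoxia replicate 1 (0.104) or p35S hypoxia replicate 1 (0.280). In all 398 probe sets were higher and 256 lower, 654 together. Higher calls were 60.9%, and 51.1% with arrays centred on their medians. The count was 49 and 141 without total replicates 1 and 2, 375 and 239 without p35S replicates 1 and 2, and 0 by limma from the compared arrays alone.

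The difference between the hypoxia responses of p35S polysomal and total RNA was called for 3 probe sets. AT3G01730 differed by 2.35 ± 0.26, with -2.53 in total RNA and -0.18 in polysomes. Its level went from 7.74 to 5.20 log2 units in total RNA, and in p35S polysomes it stood at 5.37 in air and 5.20 in hypoxia. There were 2 unnamed probe sets with differences of -2.31 and -1.80. The low-oxygen list had a median difference of 0.89, with 0 of 13 genes called over all probe sets by limma and 0 adjusted over the list alone. Its adjusted p was 0.00252, and adjusted p = 0.260 with an estimated correlation. As this list was named in literature that partly used these samples, its difference is not independent evidence. Fry gave 0.177, and without total hypoxia replicate 1 camera gave 0.0746. The count was 0 without total hypoxia replicate 2, p35S control replicate 2 or p35S hypoxia replicate 2, and from the compared arrays alone. It was 1 without total control replicate 1, 12 without p35S hypoxia replicate 1 and 9 with trended robust moderation.

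Which transcripts differ between the cells of each line was asked in air. In endodermal pSCR polysomes against p35S, AT3G03680 (3.47 ± 0.44 log2 units), AT1G73620 (3.44 ± 0.55), AT4G17280 (3.16 ± 0.63), AT2G39430, a dirigent-family gene (3.08 ± 0.64), XTH16 (2.76 ± 0.30) and the peroxidase Prx37 (2.63 ± 0.43) were higher. So were AT5G45480 (2.61 ± 0.61), the peroxidase AT5G66390 (2.60 ± 0.61), AT5G52790 (2.59 ± 0.31), AT4G24140 (2.58 ± 0.37), PDF2.5 (2.58 ± 0.47) and AT3G14470 (2.57 ± 0.50). Among these, AT5G52790 (2.21 and 2.84) and PDF2.5 (2.22 and 1.80) were also called higher than p35S in pSHR and pWOL. They do not set pSCR apart from those lines. Of the endodermis list GSO1 was 2.32 and JKD 1.91 higher, and the cortex marker AT1G09750 was 2.24 higher. AT2G43550 (-3.61 ± 0.35), AT3G61930 (-3.51 ± 0.39), AT3G06460 (-3.46 ± 0.56) and the jacalin-type lectin genes AT1G52050 (-3.46 ± 0.56), AT1G52060 (-3.33 ± 0.52) and AT1G52070 (-3.14 ± 0.38) were lower. So were AT4G02850 (-3.29 ± 0.54), AT1G31335 (-3.27 ± 0.39), AT3G18280 (-3.24 ± 0.51), GSTU23 (-3.22 ± 0.26), LCR69 (-3.18 ± 0.38) and AT4G27400 (-3.08 ± 0.56). The stele genes PHV (-1.12) and LHW (-1.07) and EXPA4 (-2.97) were lower as well. No list passed, the smallest adjusted p being 0.103 for the cell wall genes. The 3 prime minus 5 prime difference of the air arrays was 3.95 and 4.14 in pSCR and 3.87 and 3.16 in p35S. The fit called 1005 higher and 1257 lower, 2262 together. Higher calls were 44.4%, and 53.4% with arrays centred on their medians. The count was 750 and 1272 without p35S control replicates 1 and 2, 756 without pSCR control replicate 1, and 1387 from the compared arrays alone.

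In vascular pSHR polysomes against p35S, AT1G36060 (3.19 ± 0.54), AT2G41380 (2.99 ± 0.38), AT2G28240 (2.80 ± 0.56), AT3G59710 (2.80 ± 0.47), AT4G31000 (2.74 ± 0.37) and AT2G28790 (2.66 ± 0.35) were higher. So were AT2G43800 (2.66 ± 0.36), AT4G03230 (2.64 ± 0.31), AT5G58200 (2.56 ± 0.57), AT3G15240 (2.51 ± 0.28), AT1G53340 (2.36 ± 0.34) and AT1G20390 (2.33 ± 0.52), and the cortex marker AT1G09750 was 2.3 higher. The stele and phloem genes LHW (-0.65), PHV (-0.37) and OPS (0.00) did not pass. AT3G49190 (-4.00 ± 0.37), AT1G52070 (-3.67 ± 0.38), AT1G52050 (-3.60 ± 0.56), AT1G52060 (-3.57 ± 0.52), AT4G27400 (-3.14 ± 0.56) and AT2G37540 (-3.03 ± 0.49) were lower. So were AT3G61930 (-2.93 ± 0.39), AT3G06460 (-2.89 ± 0.56), AT4G22640 (-2.84 ± 0.41), AT5G54370 (-2.82 ± 0.60) and AT1G50060 (-2.73 ± 0.61). BPC1, a BASIC PENTACYSTEINE transcription factor, was lower by at least 8.8-fold (-3.14 ± 0.26), its pSHR level lying near the lowest array value of 3.35. It stood at 4.23 to 4.46 log2 units in the 4 pSHR arrays and at 6.87 to 9.49 in the other 16. Its neighbour ATMAP65-6 stood at 9.62 to 10.34 in pSHR and 8.52 to 10.54 elsewhere. Against total RNA in air, the p35S arrays used here had a median of 0.84 for the fermentation list. In pSHR against p35S the fermentation list had a median of -0.60, with 0 of 4 genes called over all probe sets by limma and 0 adjusted over the list alone. The adjusted p was 0.0344, and adjusted p = 0.189 with an estimated correlation. It was not called without p35S control replicate 2 (0.227) or pSHR control replicate 2 (0.291). In RNA quality, the 3 prime minus 5 prime difference of the air arrays was 4.35 and 4.52 in pSHR and 3.87 and 3.16 in p35S. The fit called 298 higher and 271 lower, 569 together. The count was 66 and 189 without p35S control replicates 1 and 2, 298 and 114 without pSHR control replicates 1 and 2, 215 without both pSHR arrays numbered 2, and 0 by limma from the compared arrays alone.

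**Figure D3:**
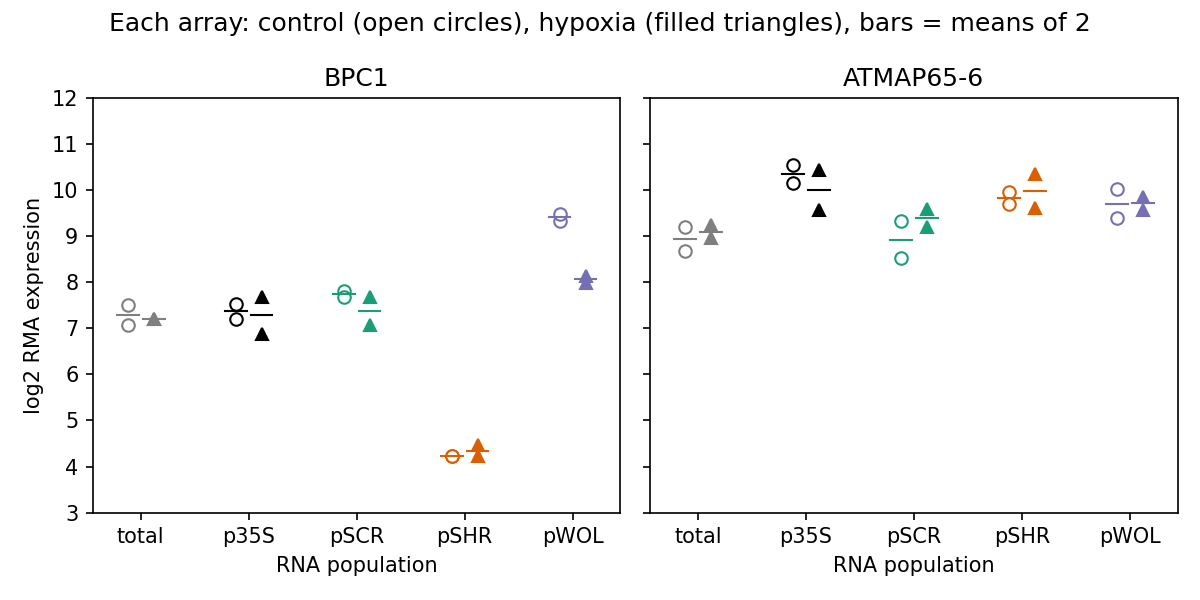
Log2 expression (vertical axis) of BPC1 and of its neighbour ATMAP65-6 on each array, by RNA population (horizontal axis); open circles are control and filled triangles hypoxia arrays, and bars are the means of 2. BPC1 lies at 4.23 to 4.46 in pSHR and at 6.87 or above elsewhere, and ATMAP65-6 in pSHR lies within the range of the other arrays.

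In vascular pWOL polysomes against p35S, AT5G02350 (3.77 ± 0.59), AT5G57080 (3.76 ± 0.63), AT2G28240 (3.75 ± 0.56), AT4G01740 (3.69 ± 0.62), AT1G70620 (3.65 ± 0.53) and AT4G19370 (3.45 ± 0.53) were higher. So were AT1G53340 (3.45 ± 0.34), AT1G09750 (3.39 ± 0.32), AT2G23330 (3.38 ± 0.41), AT4G36980 (3.37 ± 0.57), AT5G25560 (3.36 ± 0.48) and AT5G54040 (3.33 ± 0.38). AT1G09750 is listed as a cortex marker and JKD, of the endodermis list, was 2.59 higher, while the stele genes LHW (-1.26) and PHV (-0.78) were lower and the phloem gene OPS (-0.28) did not pass. The lower genes also included sks15 (-4.89 ± 0.75), AT1G52070 (-4.44 ± 0.38), AT3G06460 (-4.41 ± 0.56), AT1G52050 (-4.09 ± 0.56), AT1G52060 (-4.02 ± 0.52) and AT4G27400 (-3.95 ± 0.56). GH9B6, an endoglucanase (-3.80 ± 0.78), AT1G50060 (-3.69 ± 0.61), AT1G23160 (-3.68 ± 0.36), AT3G19430 (-3.63 ± 0.59), AT2G37540 (-3.63 ± 0.49) and AT3G49190 (-3.54 ± 0.37) were lower too. The fermentation list was lower, with a median of -1.16, 3 of 4 genes called and 4 adjusted over the list alone, and PDC2 at -1.22. Its adjusted p was 0.00132, and adjusted p = 0.0637 with an estimated correlation. Against the same p35S arrays this list also had a median of -0.60 in pSHR and, without passing, -0.49 in pSCR. In p35S against total RNA in air it was 0.84. Part of the pWOL difference may therefore come from the shared p35S arrays. The comparison of pSHR with pWOL, which leaves p35S out, had a median of 0.54. Between the air arrays of pWOL and p35S the 3 prime minus 5 prime difference was 4.39 and 5.07 against 3.87 and 3.16. The fit called 1511 higher and 1329 lower, 2840 together. The count was 1214 and 1437 without p35S control replicates 1 and 2, and 1452 and 1347 without pWOL control replicates 1 and 2.

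Across the 3 lines, 121 probe sets were higher than in p35S in all 3 and 128 lower. Independent lists would share 0.87 and 0.88, but these lists use the same p35S arrays and are not independent. In 20 simulations of unchanged groups against the same controls the count was 0. That was largely fixed in advance, since unchanged groups give few adjusted calls. These values are therefore not a fair expectation. At an unadjusted p below 0.05 the counts were 662 and 733, against 53.5 and 51.5 in the same simulations, which held no real change in any line. The p35S controls are 2 arrays and could not be split, so part of the excess may come from the shared controls. The p35S arrays also had the lowest 3 prime minus 5 prime difference of the 5 populations (mean 3.68 over both treatments).

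In pSCR polysomes against the mean of the vascular lines, AT2G39430 (3.18 ± 0.55), AT3G22620 (2.80 ± 0.44), AT1G30750 (2.74 ± 0.46), the peroxidase AT5G66390 (2.71 ± 0.52) and AT4G21820 (2.70 ± 0.45) were higher, and the endodermis gene GSO1 was 1.68 higher, while JKD of the same list (-0.16) did not pass. AT2G43550 (-3.12 ± 0.30), AT3G45160 (-3.00 ± 0.41), AT2G17350 (-2.90 ± 0.52), AT3G18280 (-2.90 ± 0.44) and AT1G31335 (-2.87 ± 0.34) were lower. In all 619 were higher and 784 lower, 1403 together. The share of higher calls was 44.1%, and 60.8% with arrays centred on their medians. The count was 177 and 779 without pSCR replicates 1 and 2, 581 without pSHR replicate 2, 822 and 829 without pWOL replicates 1 and 2, and 423 from the compared arrays alone. Without both pSHR arrays numbered 1 or 2 it was 2476 and 827.

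Between the vascular lines, AT5G20950 (2.91 ± 0.63), AT3G05060 (2.42 ± 0.47), AT5G19110 (2.3 ± 0.43), AT1G13730 (4.3-fold) and AT2G20420 (2.1 ± 0.28) were higher in pSHR than in pWOL. BPC1 was lower in pSHR by at least 36.4-fold (-5.19 ± 0.26), and AT5G43180 (-2.45 ± 0.32), AT1G07300 (-2.43 ± 0.56), AT4G19370 (-2.42 ± 0.53) and AT5G02360 (-2.35 ± 0.33) were lower as well. The fermentation list had a median of 0.54, with 0 of 4 genes called over all probe sets by limma and 0 adjusted over the list alone. Camera's adjusted p was 0.0311, and adjusted p = 0.186 with an estimated correlation. It missed the threshold under quantile normalization (0.0595) and without pSHR control replicate 1 (0.247) or pWOL control replicate 2 (0.154). The fit called 203 higher and 246 lower, 449 together. The count was 1 and 676 without pSHR replicates 1 and 2, 61 and 11 without pWOL replicates 1 and 2, and 1 from the compared arrays alone. Without both pSHR arrays numbered 1 or 2 it was 3 and 1171.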

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

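The tests of the pSHR replicates, of BPC1 and of chance deviation in the p35S arrays were chosen after the values were seen, and the last was parted by line, and its bound set on every array pairing, after its values were known; those of loss in immunopurification, of the 3 prime bias and of other splits were written before, and the reading of the first was narrowed after its values were known.

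Differences between lines in the response to hypoxia stood out because a test of the difference itself passed. These were 36 probe sets in pWOL against p35S, 6 in pSCR against p35S and 3 between p35S polysomal and total RNA. From the arrays of the compared groups alone each of these counts was 0. The joint F test of the 3 line differences from p35S called 0 probe sets, its smallest adjusted p being 0.0830. In pWOL the named genes were SETH6 (-4.16), AT2G32190 (-3.84), AT3G07230 (-2.82), AT2G17850 (-2.81), AT3G03150 (-2.76), AT3G18190 (2.37), AT1G50920 (2.11), AT1G15480 (1.93), ATERDJ3B (1.85) and SLOMO (1.67). In pSCR they were AT5G23340 (2.04), AT1G36070 (-1.83), AT3G54080 (1.74) and AT4G26460 (-1.41), and between polysomal and total RNA AT3G01730 (2.35). In p35S polysomes AT3G01730 stood in air (5.37) near the level that total RNA reached in hypoxia (5.20). Whether a floor limited its fall there was not tested, and the lowest array value was 3.35. The low-oxygen list differed by a median of -1.24 in pWOL, -0.69 in pSHR and 0.89 between polysomal and total RNA, and the oxidative stress list by -0.86 in pSCR. With an estimated correlation none of these list calls held (adjusted p = 0.175, 0.212, 0.260 and 0.129). The low-oxygen list had a median difference of -0.44 in pSCR and was not called there. Because literature that partly used these samples named the list, its differences are not independent evidence. All these differences share the p35S arrays. The hypoxia difference of AT4G26460 was 1.47 in p35S and 0.06 to 0.38 in the other populations. That of AT2G32190 was 3.47 in p35S and -0.37 to 0.71 in the others. For SETH6 it was 0.15 in total RNA, 0.64 in p35S and -3.52 in pWOL, and for AT3G18190 it was 0.23, -0.44 and 1.93.

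The pSHR arrays numbered 1 and 2 lie apart, by 0.67 log2 units in air and 0.86 in hypoxia, on an axis of 413 probe sets higher in pSCR and 556 higher in pWOL, which was chosen from the pSCR and pWOL arrays alone and on which pWOL stood at -0.96 and -1.07 in air and -0.47 and -0.46 in hypoxia. A swap with an array of another line would bring that line's BPC1 level, yet the highest pSHR array lies 2.41 below the lowest other array. RNA of another line mixed into the samples numbered 1 would raise BPC1 in them, where the largest difference was 0.23; both readings take the low BPC1 as a property of the line. A batch shared by equal numbers would show in total and p35S arrays, where the largest difference was 0.10 in size. A difference in harvest or in the cells of these plants stays open and was not tested.

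BPC1 is the only probe set more than 2 log2 units below all other arrays in every array of 1 population. Failed or differently scaled pSHR arrays would displace other transcripts, and 0 others lay more than 1 log2 unit below; a deletion reaching the neighbour ATMAP65-6 would lower it, and 4 of 4 pSHR arrays lay within the range of the others. If pWOL samples vascular cells as labelled, low BPC1 in those cells of every line would lower it in pWOL, whose arrays lay above the p35S arrays of the same treatment by at least 0.29. An earlier form of this last test, which asked for a mean difference over 1 in both treatments, gave 2.04 in air and 0.78 in hypoxia and left it undecided, and the bound was changed after these were seen. A lesion at BPC1 in the pSHR line, or a difference between the cells marked by pSHR and pWOL, was not tested.

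Of 579 transcripts lower in p35S polysomes than in total RNA in air, 203 were higher in at least 1 other line than in p35S, and the p35S control arrays, which enter both comparisons, may be low in them by chance. In the hypoxia arrays, which did not choose them, that explanation predicts a median of line minus p35S near 0, and the median was 0.01 in pWOL (0.00 to 0.07 over array pairings), 0.27 in pSCR (0.22 to 0.33), which it does not predict, and 0.01 in pSHR, where the range of -0.19 to 0.22 leaves it undecided. Against total RNA in hypoxia the medians were -0.50, -0.80 and -0.75 for pSCR, pSHR and pWOL and -0.82 for p35S, which loss in every immunopurification and low ribosome loading both predict, and neither accounts for levels above p35S, so this test left loss undecided. Weaker 3 prime bias of the p35S arrays was left undecided, the array with the smaller bias differing by 0.02 in air and 0.09 in hypoxia. The cells in which p35S is active differ from those of the other lines by design, which was not tested.

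For the mean polysomal hypoxia count of 4669, 100 splits of each line's 4 arrays into 2 and 2 were compared. Only 1 (the real one) gave as many, and the highest of the others gave 2072. The other splits mix hypoxia and control arrays or reverse a line, so a hypoxia effect itself lowers their counts. The real split's share could not fall below 1 of 100, so chance cannot be called excluded. The splits also cannot tell whether the arrays of a group came from separate cultures.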

How the results depend on the processing

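The settings that leave out both pSHR arrays of 1 number, and the crossed lysate pairing, were chosen after seeing the data. None of 359 results for named genes in a comparison, and none of the 33 list calls, turned direction under any alternative run. This was largely fixed in advance. Settings that keep the values of the compared arrays leave their group means, and so the list medians, unchanged. Calls without overlap between the arrays keep their sign when 1 array is left out. Of 4895 gene values under alternatives 643 lost the threshold, among them 115 of 359 from the compared arrays alone 29 of 51 with the replicate block of the shared lysate, and 409 of 2056 with 1 array left out, where a lone array is assumed to vary like the other groups. Signal over background was not used here, so weak signal was examined only by leaving out the dimmest 25% of probe sets, where 5 of 357 gene results lost the threshold. Except where fewer arrays or probe sets were used, the cause was not tested.

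Leaving out 1 array at a time gave these lowest and highest counts of called probe sets. Hypoxia gave 309 to 443 in total RNA, 514 to 1179 in p35S, 475 to 1105 in pSCR, 382 to 1539 in pSHR, 788 to 871 in pWOL and 3873 to 4732 for the polysomal mean. The differences from p35S gave 0 to 33 in pSCR, 0 to 55 in pSHR and 0 to 156 in pWOL, and the F test 0 to 7. Polysomal against total RNA gave 429 to 660 in air, 49 to 375 in hypoxia and 0 to 12 for the difference between treatments. Against p35S in air, pSCR gave 750 to 1532, pSHR 66 to 298 and pWOL 1214 to 1452. The pSCR against vascular count was 177 to 1998 and the pSHR against pWOL count 1 to 676.

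With single-gene probe sets only, which are fewer, hypoxia gave 296 in total RNA, 512 in p35S, 650 in pSCR, 451 in pSHR, 894 in pWOL and 2328 for the polysomal mean. Polysomal against total RNA gave 697 in air, 303 in hypoxia and 1 for the difference between treatments. The lines in air gave 1049 (pSCR), 259 (pSHR) and 1382 (pWOL) against p35S, 642 for pSCR against vascular and 196 for pSHR against pWOL. With the arrays of the compared groups only, hypoxia gave 342 in p35S, 228 in pSCR and 20 in pSHR. That setting gave 1 in the F test, 0 for the pSCR and pWOL differences from p35S, and 0 for polysomal against total RNA in hypoxia and for its difference between treatments. The lines in air gave 1387 for pSCR and 0 for pSHR against p35S, 423 for pSCR against vascular and 1 for pSHR against pWOL. Leaving out the dimmest 25% of probe sets gave 0 for the pSCR difference from p35S. Trended robust moderation gave 7 for the pSHR difference, 9 for polysomal against total RNA between treatments and 14 in the F test. Without both pSHR arrays numbered 1 the pSHR difference gave 2, pSCR against vascular 2476, pSHR against pWOL 3 and the F test 4. Without both numbered 2, pSHR hypoxia gave 244, pSHR against p35S 215, pSCR against vascular 827 and pSHR against pWOL 1171.

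Over all groups replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.33 to 0.29, the highest between pSHR control and hypoxia, and 11 of 45 pairs of groups were over 0.1. With a replicate block the pWOL difference from p35S gave 0 and no other count moved by over 1.5 times. A replicate block of the shared lysate gave 265 for polysomal against total RNA in air, 0 in hypoxia and 0 for the difference between treatments, and the crossed pairing gave 1201 in air.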

Other observations

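The gene lists in this part were chosen after the data were seen. Class III peroxidases, as a whole family, moved in both directions in the mean polysomal hypoxia comparison: of 55 measured genes 19 fell and 6 rose, and 18 fell and 6 rose under quantile normalization and with arrays centred on their medians. Beside those already named, AT4G11290 (-1.41 ± 0.23) and AT2G41480 (-1.18 ± 0.13) fell, whereas AT5G39580 rose by 2.97 ± 0.13 and Prx37 by 1.41 ± 0.22. AT5G39580 also rose in each population alone, by 2.48 in pWOL to 3.71 in p35S. The family's camera adjusted p, within the added lists, was 0.0213, and adjusted p = 0.844 with an estimated correlation. The root hair genes EXPA7 (-2.23) and EXPA18 (-1.74) fell in the same comparison. The family was also called for hypoxia in pSHR (8 fell, 1 rose; adjusted p 0.00573) and pSCR (6 fell, 1 rose; 0.0389) and in p35S polysomes against total RNA in hypoxia (2 lower, 2 higher; 0.00573), each with adjusted p = 0.844 with an estimated correlation. In air, pSCR against p35S, 8 members were higher and 8 lower (camera adjusted p within the added lists 0.375), with AT4G11290 (2.08) and AT1G68850 (1.78) among the higher and AT2G43480 (-1.72), PRXR1 (-1.42) and AT2G41480 (-1.28) among the lower.

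Plastid-encoded transcripts (69 measured) had a median of -0.21 in p35S polysomes against total RNA in air, with psbJ among 2 called genes, and of 0.26 for hypoxia in pWOL, with 2 called; adjusted over the list alone 0 passed in limma in either. The camera adjusted p within the added lists were 0.0338 and 2.70e-04, and adjusted p = 0.844 with an estimated correlation in both. In p35S polysomes against total RNA in hypoxia the median was 0.03, with an adjusted p of 0.845. For hypoxia the list did not pass in total RNA (-0.12, adjusted p 0.375), p35S (0.13, 0.194) or pSHR (-0.05, 0.650), and in pSCR it had a median of 0.18 with an adjusted p of 0.0362, and adjusted p = 0.844 with an estimated correlation. It was also called for the mean polysomal hypoxia difference (0.11, adjusted p 0.0104), the pWOL difference from p35S (0.26, 0.0242), the difference between polysomal and total responses (0.22, 0.0389) and pSHR against pWOL in air (0.13, 0.0104), all with adjusted p = 0.844 with an estimated correlation.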
